A study of Mus musculus with 4 samples.

How the data were processed

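Hi-C libraries of CD1 mouse sperm were described in the labels as 4 samples of 1 group, 2 titled biological and 2 technical. Per the labels' protocols, fixation was in 1% formaldehyde over 10 min, HindIII cut the chromatin, and biotin-filled ends were ligated and sequenced. Per the submitters' processing notes, BWA was used and the build was mm9. The aligner's version, the filters on read pairs, the treatment of duplicates and the normalization method are not given in the sources used here. The authors deposited 40 files of normalized contact signal, 1 for each of 2 maps and 20 chromosomes (1 to 19 and X), each a symmetric matrix of 100 kb bins named by mm9 positions per the file headers. No file column names a single library, so the maps could not be tied to the samples and each is treated as a pooled value of the group. The number of maps gives no estimate of variation between animals, and p-values below describe positions along chromosomes or differences between chromosomes.

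The deposited signal was not scaled to a common total, and bin sums were unequal (median 3.01 on the autosomes and 1.51 on X in map 1, and 1.94 and 1.09 in map 2). There were 3 values below 0 in map 1 and 4 in map 2, the lowest -6.5e-07, and these were set to 0. Each value was found to be a whole number times a factor of each of its 2 bins: among low values, 99.999% in each map came within 0.05 of a whole number, where 10% would by chance. The whole numbers were taken as recovered contacts and used for depth, thinning and the comparison of counting error only. They are approximate for large values, and whether contacts within a bin were entered 1 or 2 times is not known. All other values were computed from the deposited signal.

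Bins with less than 0.25 of the chromosome's median summed signal at separations up to 2 Mb in either map were left out. The mean map is the average of the maps after each was scaled to the same total between bins per chromosome. Expected contact was the mean at the same separation, pooled over separations within 5%. The decay exponent is the slope of log10 mean signal on log10 separation over 20 log-spaced intervals. Compartments are the sign of the leading eigenvector of the correlation matrix of observed over expected contact, with class 1 the class of fewer bins. Compartment strength is the mean observed over expected contact within the top 20% and within the bottom 20% of bins by eigenvector, averaged and divided by that between them, at separations above 2 Mb. The insulation score is the log2 mean signal between the 500 kb on either side of a bin over the chromosome median, and boundaries are its local minima with a prominence of at least 0.1. Contact between chromosome ends compares the first and last 5 Mb with data, with an expected value from other pairs of the same separation or, where there were none, from a power law fitted at separations over 20 Mb.

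Agreement of classes and boundaries was tested with 100000 circular shifts within chromosomes (one-sided), chromosome ends with 100000 sign flips over 19 autosomes (two-sided), and X by its exact position among 20 chromosomes (two-sided), for which 0.1 is the smallest p. The regions named were set by a rule before the data were examined: the 10 boundaries of largest prominence called in both maps, the 5 longest runs of each class with the same class in both maps, per map the 5 bin pairs over 20 Mb apart with the highest observed over expected contact averaged over 3 by 3 bins where both maps exceeded 2-fold, and the 5 runs where the eigenvectors differed most. Neighbouring pairs within 10 bins were counted as 1 pair. Runs of difference were stretches of bins in the top percent of differences. Compartment strength and near signal of X against the autosomes, blocks of 2 Mb, balancing, thinning and the limit on high bins were added after seeing the data. Alternatives covered ranges, windows, thresholds, bin size, every bin kept and each map alone.

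A gene annotation of mm9 was not used here, since the gene table at hand is of build GRCm38.p6. The planned comparisons of gene density by compartment and at boundaries and of gene lists by compartment were therefore not run, and regions are given by position. Contacts between chromosomes are not analysed here. Steps were tested on a simulated chromosome 18 of 908 bins with known classes and borders, as 2 maps at the depth and factors of map 1 and map 2. In simulated map 1 the count was recovered exactly for 100.0% of pairs of different bins, those without contacts included. Counts within a bin were not checked. In the mean of the simulated maps, 100.0% of bins had the simulated class and 88.9% of 81 borders were found. Of 96 calls in that mean, 75.0% were at a simulated border and 100.0% at a border or a class switch. With the decay alone and no factors, the exponent came out at -1.20 for a simulated -1.2. Python 3.11.15 with numpy 2.4.6, scipy 1.17.1, pandas 2.3.3 and matplotlib 3.10.9 was used.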

Results

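Hi-C, in which DNA fragments that lay close together in crosslinked nuclei are ligated and sequenced as pairs, was applied to sperm of CD1 mice, an outbred stock. The series holds 4 libraries of 1 group, titled replicates 1 to 4, of which 2 are titled biological and 2 technical. Cells were fixed with 1% formaldehyde for 10 min and the chromatin was cut with HindIII. The deposited values form 2 contact maps, called map 1 and map 2 here, of 19 autosomes and X in 26398 bins of 100 kb on mouse build mm9. Which libraries entered which map is not given in the sources used here, so each map's value is printed as the authors' value without an SD. The steps between the values corresponded to about 193268655 contacts in map 1 and 124797310 in map 2, of which 68529406 and 39362948 joined different bins of a chromosome. The totals are too high if contacts within a bin were entered 2 times, which is not known. The series title names the regulatory landscape that sperm chromatin carries forward, and the maps describe its folding along each chromosome.

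The first question was how far the maps matched, since the labels name no treatment. Of 25474 bins, 24871 (97.6%) had the same compartment class in the maps, against a mean of 50.2% and a highest value of 58.9% over circular shifts of one map's track (permutation test, one-sided, p = 1e-05, the smallest that 100000 shifts can give). Chromosome 5 had the highest share of bins with the same class among the autosomes (98.5%) and chromosome 16 the lowest (97.1%). X, which also had the fewest contacts per bin, stood below all of them at 94.8%. For single pairs of bins, the correlation of the maps at equal separation up to 10 Mb had a median of 0.487 over the 20 chromosomes, from 0.355 on chromosome 7 to 0.622 on chromosome 12. After averaging over 3 by 3 bins it was 0.835.

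Contact fell steeply with separation on every autosome and in both maps. Between separations of 1 and 10 Mb the mean signal fell 15-fold in map 1 and 15.7-fold in map 2 (autosome medians), and between 10 and 50 Mb it fell by a further 2.18-fold and 2.24-fold. The exponent of the decay from 0.5 to 7 Mb was -1.29 in map 1 and -1.30 in map 2, with -1.29 for the mean of the maps and an SD of 0.0464 over the 19 autosomes. Chromosome 12 had the shallowest decay (-1.17) and chromosome 7 the steepest (-1.36). Contacts over more than 10 Mb made up 25% of the signal between bins in map 1 and 24.4% in map 2, from 17.8% on chromosome 19, the shortest, to 30.8% on chromosome 1, the longest (mean map). The difference in share between those chromosomes was far larger than that between the maps, whose values on chromosome 1 were 31.2% and 30.3%. A longer chromosome has more bin pairs beyond 10 Mb, so the share depends on length. Mean contact per bin pair at 10 to 50 Mb over that at 0.5 to 2 Mb had the reverse order. It was 0.0473 on chromosome 1 and 0.0721 on chromosome 19, the highest of the autosomes (mean map).

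**Figure D1:**
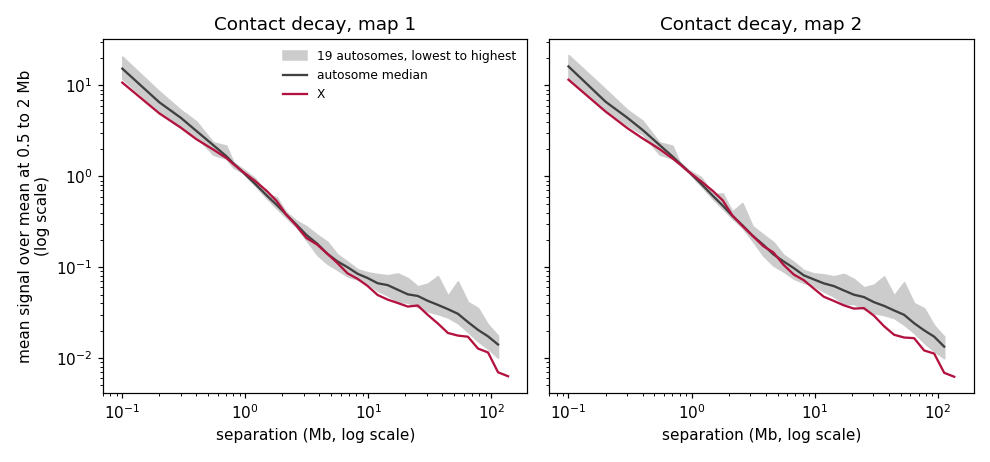
Mean normalized contact signal at each separation over the chromosome's own mean at 0.5 to 2 Mb, in map 1 (left) and map 2 (right), both axes on a log scale. The grey band spans the 19 autosomes, the dark line is their median and the red line is X, which runs along or below the lower edge of the band at separations above 10 Mb.

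X, of which a male cell holds 1 copy before meiosis and about every other sperm holds 1, was set against the autosomes. X had fewer contacts per bin than any autosome, 1337 in map 1 and 790 in map 2, or 0.479 and 0.495 of the autosome medians. Its contacts at 10 to 50 Mb were the lowest of the 20 chromosomes relative to those at 0.5 to 2 Mb, with a ratio of 0.0322 in map 1 and 0.0306 in map 2, against autosome medians of 0.0479 and 0.0468 and a lowest autosome, chromosome 13, at 0.0401 and 0.0385. Over the range of 0.5 to 7 Mb the decay exponent of X was -1.29 in map 1 and -1.30 in map 2, in the middle of the autosomes (exact permutation test for the mean map, two-sided, p = 1), whereas its fall between 1 and 10 Mb, 17.9-fold and 19.4-fold, was above the highest autosome (17.7-fold and 18.6-fold). The exact permutation p for the ratio was 0.1, the smallest that 1 chromosome among 20 can give, so the test cannot pass 0.05. Without bins over 3 times the median near-diagonal sum, a setting chosen after seeing the data, X was not the lowest, and its log2 ratio to the autosome median went from -0.59 to -0.30 (exact permutation p = 0.2). From 0.2 to 2 Mb the exponent of X was 0.21 above the autosome median and above every autosome (exact permutation p = 0.1).

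Chromosomes were split into alternating blocks of 2 classes that contacted their own kind and avoided the other. The longest block of class 1, the class with fewer bins on each chromosome, ran on chromosome 4 from 128300001 to 142700000 (14.4 Mb), followed by chromosome 15 from 72800001 to 86400000 (13.6 Mb) and chromosome 11 from 6800001 to 19700000 (12.9 Mb). The longest block of class 2 also lay on chromosome 4, from 63600001 to 80800000 (17.2 Mb), followed by chromosome 13 from 34000001 to 49800000 (15.8 Mb) and chromosome 9 from 52600001 to 67900000 (15.3 Mb). Chromosome 12 from 76500001 to 88800000 and chromosome 2 from 24100001 to 36100000 completed the 5 longest blocks of class 1, and chromosome 1 from 95900001 to 107500000 and from 108900001 to 120200000 those of class 2. Blocks were defined by bins of the same class in both maps, with mean eigenvector values in the 2 maps of 1.04 and 1.04 on chromosome 4 for class 1 and -1.15 and -1.17 for class 2. In all, 1572 such blocks (755 of class 1 and 817 of class 2) had a median length of 0.7 Mb. Bins whose class differed between the maps were in no block, so neighbouring blocks can be of the same class. The classes carry no names, because gene density was not used to orient them, and a class on one chromosome is not tied to the same class on another.

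**Figure D2:**
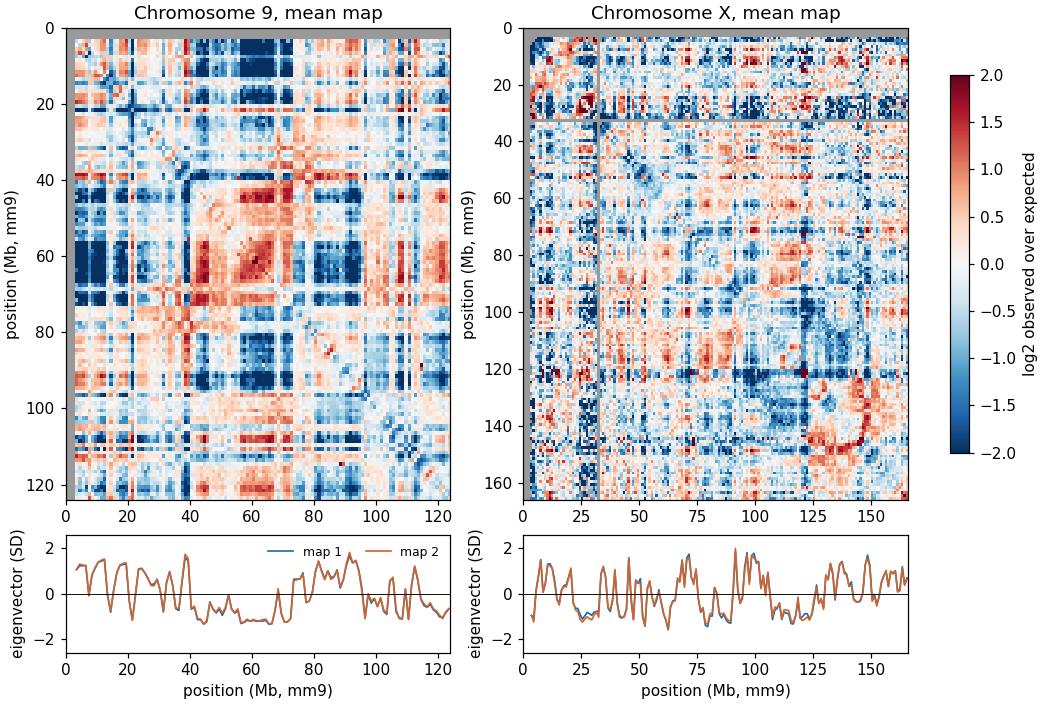
Observed over expected contact (log2, colour, limited to the range shown) of the mean map in 1 Mb bins along chromosome 9, the autosome of median compartment strength, and X, with the compartment eigenvector of each map (in SD) beneath. Grey marks positions left out for lack of signal; the blue and orange tracks of the 2 maps overlie each other on chromosome 9.

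The contrast between the classes differed by chromosome. It was highest on chromosomes 17, 11, 2 and 15, where contacts within the 20% of bins at either extreme of the eigenvector were 13.1, 12.7, 12.1 and 11.8 times those between the extremes at separations above 2 Mb, and lowest among the autosomes on chromosomes 13, 14 and 18 (6.13, 6.20 and 6.26). The median over 20 chromosomes was 8.64 in the mean map, 8.79 in map 1 and 8.73 in map 2, and simulated maps with the decay alone gave 1.02. Relative to the mean at the same separation, contact within the extreme bins had an autosome median of 2.28 for class 1 and 1.87 for class 2, and contact between them one of 0.239. The order differed by chromosome, with 1.92 for class 1 and 2.23 for class 2 on chromosome 9. X had the lowest strength of all chromosomes, 5.14 in map 1 and 5.80 in map 2, and the highest contact between its classes, 0.366 times the mean at the same separation. Its eigenvector also held only 3.95% of the variance, against 11.6% to 22.6% on the autosomes. That share is not given here for autosomes thinned to the contacts of X, so a weaker axis was not told apart from sparser counts. The exact permutation p of the position of X in strength was 0.1, again the smallest possible, and the comparison was chosen after the values were seen.

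**Figure D3:**
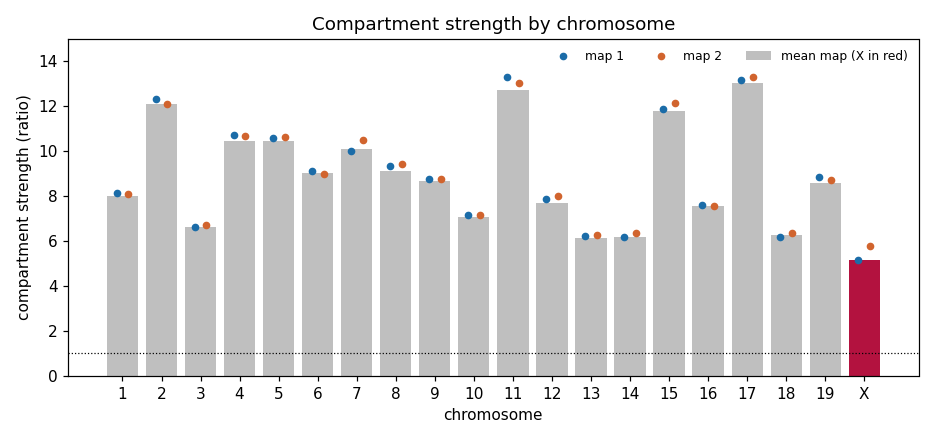
Compartment strength, the ratio of contact within to contact between the 20% of bins at either extreme of the eigenvector, per chromosome. Bars show the mean map from 0, points show each map, and the dotted line is a ratio of 1; X, in red, is below the 19 autosomes.

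Sharp borders, across which contact dropped, were found on each chromosome, and those named here were called in both maps. The deepest was on chromosome 12 from 25000001 to 25100000, where the insulation score, the log2 contact across a bin within 500 kb over the chromosome median, was -4.81 and the prominence of the minimum 6.26 on the log2 scale (6.15 in map 1 and 6.39 in map 2). Chromosome 8 from 114500001 to 114600000 had a prominence of 6.06, chromosome 4 from 113900001 to 114000000 one of 5.95, chromosome 5 from 109200001 to 109300000 one of 5.65 and chromosome 19 from 53000001 to 53100000 one of 5.57. The other named borders were on chromosome 12 from 70200001, chromosome 10 from 7200001, chromosome 5 from 125900001, chromosome 4 from 126900001 and chromosome 7 from 123700001, with prominences of 5.54, 5.47, 5.40, 5.27 and 5.24. The maps differed most at the last, with 5.10 in map 1 and 3.38 in map 2. All 10 were also called after the maps were balanced to equal bin sums, with prominences from 2.38 to 5.11. The correction factor at the deepest border was 1.96 times the median, and at the others it ran from 0.58 to 1.63 times. The highest factor within 500 kb ran from 1.11 times the median to 3.78 times, the latter on chromosome 4 near 113900001. Sequence placed differently in these mice and in mm9 was not tested for the borders and stays open.

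In total 3596 boundaries with a prominence of at least 0.1 were called in the mean map, at a median spacing of 600 kb. Of 3581 boundaries of map 1, 3261 (91.1%) had a boundary of map 2 within 1 bin, against a mean of 42.4% and a highest value of 48.9% over circular shifts (permutation test, one-sided, p = 1e-05, the smallest that 100000 shifts can give). Chromosome 11 had the most boundaries per Mb with data (1.61) and chromosome 14 the fewest (1.32), and 82.5% of those on X recurred in map 2 against 89.4% to 96.3% on the autosomes. The score of map 2 averaged -0.65 at boundaries of map 1 and 0.10 and 0.11 at 500 kb on either side. Simulated maps with the decay alone and independent counts gave 567 boundaries at this threshold, 15.8% of the number called. They gave 100 against 3069 at a prominence of 0.2. On X, at the main threshold, they gave 75 where 219 were called. These simulated maps lacked compartment classes as well as borders, and class switches alone can give calls. The deposited maps also differed by more than counting error. The simulated numbers are therefore not a rate of false calls and may be too low.

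**Figure D4:**
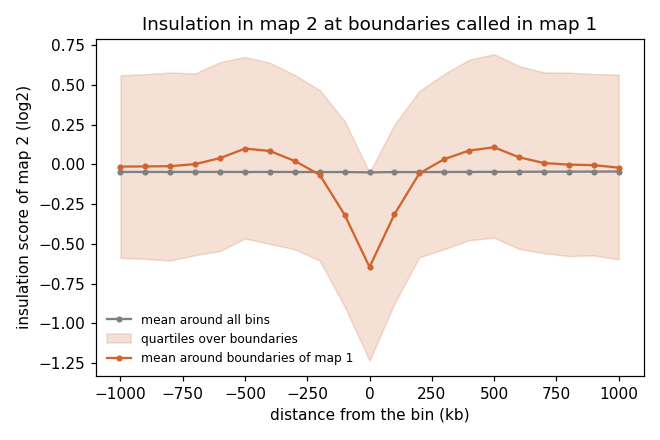
Insulation score of map 2 (log2 contact over the chromosome median) by distance in kb from the 3581 boundaries called in map 1, as the mean (orange line) with quartiles (shading), and around all bins (grey). The mean falls to -0.65 at the boundary bin.

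Contact between the 2 ends of a chromosome, which in the mouse lie next to the centromere and at the distal telomere, was above expectation on some autosomes and below it on others. On chromosome 17 the first and last 5 Mb with data met less often than expected, with a log2 observed over expected of -1.43 in map 1 and -1.35 in map 2, and on chromosome 9 the values were -0.68 and -0.98. On chromosome 11 they met more often, at 0.59 and 0.57, and on chromosome 3 at 0.26 and 0.33. The sign was the same in both maps on 15 of 19 autosomes. The mean over the autosomes was -0.22 with an SD of 0.47 (permutation test by 100000 sign flips, two-sided, p = 0.0557), and 6 of 19 values were above 0. Map 2 alone gave -0.25 (permutation p = 0.0298) and map 1 alone -0.19 (permutation p = 0.113), so no departure is called. Other pairs of the same separation gave the expected value for 49.0% of the bin pairs in these corners (autosome median), and the remainder rests on a fitted power law.

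A few distant bin pairs stood far above the expected contact in both maps, and X held the most. The pair on X of 3900001 to 4000000 and 31700001 to 31800000 had 67.2 times the expected contact in map 1 and 70.1 times in map 2, and that of 73300001 to 73400000 and 145500001 to 145600000, 72.2 Mb apart, had 49.9 and 52.8 times. On chromosome 5, the pair of 94800001 to 94900000 and 152500001 to 152600000 had 49.9 and 43.0 times. Other leading pairs differed more between the maps, such as chromosome 7 from 23100001 with the bin from 83500001, at 7.26 times in map 1 and 72.7 times in map 2. At least 10-fold contact in both maps was found for 113 pairs over 20 Mb apart, of which 46 were on X and 16 on chromosome 7. X also had the fewest contacts per bin, and no number of pairs is given here for autosomes thinned to that depth. The larger number on X was therefore not told apart from its sparser counts. In 75.2% of the 113 pairs a bin or its neighbour was among the tenth of bins with the largest correction factors of its chromosome. That held for every pair named above, and the strongest bin pair of each reached the mean contact of bins 1 Mb apart. For the leading pair on X it reached the mean of bins 0.1 Mb apart. The named pairs are therefore not shown to be contacts over long distances, and sequence placed differently in these mice and in mm9 stays open.

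Where the maps differed most, the bins were again on X. The 5 runs of bins with the largest difference of the eigenvectors were single bins of X, from 166200001 (1.74 in map 1 and 0.927 in map 2), 81700001 (-0.657 and 0.153), 46100001 (-0.749 and 0.0250), 60500001 (-1.19 and -0.458) and 165200001 (1.02 and 0.317). Of the 255 bins in the top percent of differences, 204 were on X. X also had the fewest contacts per bin, 1337 in map 1 and 790 in map 2, against autosome medians of 2792 and 1597. No difference is given here for autosomes thinned to that depth. Counting noise on X was therefore not told apart from a difference between the maps.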

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

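Tests in this part were set out before their results were seen, while the comparison of the strength of X with the autosomes was itself chosen after seeing the data, as was the use of each setting's own spread between the maps. Contacts within a single bin of 100 kb, which no comparison above uses, made up 64.5% of the recovered contacts in map 1 and 68.5% in map 2. They drew attention as signal outside the main measurement, and pairs of very short separation, which Hi-C libraries can hold without a ligation between distant sites, were not told apart here. Whether they were entered 1 or 2 times is not known, and if 2, the shares are too high.

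X had a lower compartment strength than the 19 autosomes (5.17 against 6.13 on chromosome 13 in the mean map). The gap was 1.05 in map 1 and 0.455 in map 2, the latter below the spread between the maps of 0.469. A lower contact count was tested by thinning each autosome to the contacts per bin of X. The lowest autosome in the mean map, chromosome 18, still exceeded X by 1.07, with a spread between the maps of 0.518. That gap was 1.06 in map 1 and 0.611 in map 2. Balancing every map to equal bin sums left a gap of 1.08 (0.883 in map 1 and 0.542 in map 2), with a spread of 0.357. These gaps argue against a lower count or unequal bin sums as the whole cause. With the 20% of bins of largest correction factors left out, X remained lowest by 0.382, with a spread of 0.233. That gap was smaller than the 0.961 with all bins, and was 0.252 in map 1 and 0.113 in map 2. The gap in map 2 was below the spread, so the values do not decide whether such bins are a part or the whole of the cause. No biological explanation was tested, since the labels give 1 group.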

How the results depend on the processing

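Settings that balance the maps, leave out bins over 3 times the median (high bins) or thin map 1 were chosen after seeing the data, as were all those for the strength and near signal of X, and the others before. Compartment agreement (94.0% to 98.8%) and shared boundaries (75.6% in the same bin to 94.9% within 2 bins) kept their side of the permutation threshold in every alternative run, and the number of boundaries ran from 2753 to 4448, each within 1.5 times the main 3596. The correlation of the maps was 0.659 up to 5 Mb, 0.376 up to 20 Mb and 0.835 after averaging 3 by 3 bins. The decay exponent was -1.19 over 1 to 10 Mb, -1.22 over 0.2 to 2 Mb, -1.24 after balancing and -1.28 without high bins, and -1.30 to -1.29 with either map alone. The share of contacts beyond 10 Mb was 24.7%, and became 17.9% beyond 20 Mb, 31.9% without neighbouring bins, 27.2% after balancing and 25.7% without high bins. Compartment strength was 13.1 for the outer 10% of bins on either side, 8.29 over all separations, 7.0 in 500 kb bins, 8.34 with the eigenvector of 1 map and the contacts of the other, 8.77 after balancing and 8.30 without high bins, and 8.73 to 8.79 with either map alone, judged against a spread of 0.0427 between the maps. Contact between chromosome ends passed 0.05 with a power law throughout (-0.32, permutation p = 0.0258) and without high bins (-0.24, permutation p = 0.0317), and was -0.25 to -0.19 with either map alone. It was nearer 0 with 3 Mb (-0.06, permutation p = 0.466) or 10 Mb (-0.11, permutation p = 0.275) at each end and after balancing (-0.16, permutation p = 0.16), against -0.22 in the main setting. The long-range ratio of X stayed below the autosome median (log2 -0.61 to -0.30), but X was no longer lowest without high bins (-0.30 against -0.59, exact permutation p = 0.2). Below the median too were its strength (-0.79 to -0.59) and near signal (-0.86 to -0.42), and its exponent minus the autosome median ran from 6.86e-05 to 0.209, with a p that cannot pass 0.05. The causes of these shifts were not tested. Gene density by compartment, gene density at boundaries and gene lists by compartment, with their alternatives, were not run for lack of an mm9 annotation here, and leaving out a map gives no value for comparisons of the maps. Thinning map 1 to the contacts of map 2 gave a correlation of 0.451 against 0.487. No paired analysis was possible because there is 1 group.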

Other observations

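The isolated blocks and the relation to chromosome length in this part were examined only after the data had been seen. Several blocks, which are windows of a fixed 2 Mb, had far more contact within themselves than with their surroundings. Among 24386 blocks scored by contact within the block over contact with the 2 Mb on either side, each relative to the mean at the same separation, the leading block was on chromosome 7 from 32200001 to 34200000, with a log2 ratio of 4.12 in map 1 and 4.38 in map 2. Of the 10 leading blocks, 4 were on X, 4 on chromosome 4 and the others on chromosomes 7 and 5. On X they ran from 30300001 to 32300000 (3.29 and 3.33), 51400001 to 53400000 (3.02 and 3.26), 120700001 to 122700000 (2.48 and 2.49) and 144300001 to 146300000 (2.42 and 2.49). Within the third of these, contact was 16.1 and 14.1 times the mean at the same separation, from 40731 recovered contacts, and its median correction factor was 1.09 times that of X, whereas the fourth had a factor of 3.63 and 2789 contacts. Those on chromosome 4 began at 120600001, 59900001, 145200001 and 41000001, with log2 ratios in map 1 of 3.55, 3.04, 2.81 and 2.62. The blocks on chromosomes 7 and 5 had median correction factors of 3.33 and 4.13 times those of their chromosomes. The median log2 ratio over all blocks was -0.13. The 4 blocks on X, that on chromosome 5 and that on chromosome 4 from 120600001 each hold a bin of a distant pair of at least 10-fold contact. X holds 46 such pairs, and the share of all blocks with such a bin is not given here. The overlap therefore does not show a link between the blocks and the distant pairs. Sequence placed differently in these mice and in mm9 was not tested for the blocks and stays open.

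A hypothesis that borders lie where the compartment class switches was tested. Of 968 class switches, 77.5% had a boundary in an adjoining bin or 1 bin further, against a mean of 52.1% and a highest value of 59.6% when boundaries were shifted along chromosomes (permutation test, one-sided, p = 1e-05, the smallest that 100000 shifts can give). Boundaries at switches had a median prominence of 1.60 on the log2 scale and those elsewhere 0.58, although only 19.5% of the 3596 boundaries were at a switch. In simulation a class switch alone also produced calls, so the overlap does not show that both arise from 1 mechanism.

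A relation of compartment strength to chromosome length over the 19 autosomes was looked for and not detected. Spearman's rho was 0.146 (permutation p = 0.546) and Pearson's r was 0.0803 (permutation p = 0.744). Without the 2 autosomes farthest from the median length they were 0.162 and 0.152, and 19 chromosomes are too few to exclude a weak or moderate relation. These 2 measures, each with and without those 2 autosomes, were the only ones computed for chromosome length.

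The maps differed by more than counting error. Among autosomal bin pairs 1 to 10 Mb apart, chi-square per pair was 1.5 at 10 to 14 contacts and 1.45 at 50 to 99, where independent counts gave 0.998 and 1.00. The ratio of 0.968 between those classes (SD 0.0219 over 19 autosomes) is consistent with read pairs counted more than once, since repeats raise the variance by 1 factor at every count. Autosomal pairs of 100 or more contacts had 1.38, a further fall, so 1 factor describes the excess only roughly. On X the value went the other way, from 1.40 at 50 to 99 contacts to 1.64 at 100 or more, the latter from 203 bin pairs. A term per bin and per separation was fitted to the ratio of the maps, so only differences particular to a bin pair can enter the excess. If these had the same relative size at every count and separation, the excess would rise with the count. The excess at 50 to 99 was 0.904 times that at 10 to 14 (SD 0.0654), which argues against that. The count classes were not matched for separation, so differences whose relative size varies with separation stay open. If repeats are the source, the recovered contacts overstate the number of independent ones.

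Distant pairs of at least 10-fold contact in both maps were weighed against 2 technical explanations. A large correction factor at either bin was found in 75.2% of the 113 pairs against 32.6% expected for random pairs (exact binomial test, one-sided, p = 1.94e-20), and the pairs involve 209 different bins, so they are not fully independent. In 56.6% of them the strongest bin pair reached the mean contact of bins 1 Mb apart. Neither share decides, since the pairs were chosen for high contact, which holds the factors as multipliers, and no comparison matched on contact was computed. Sequence of large correction factor and sequence placed differently in these mice and in mm9 both stay open, and no biological explanation was tested.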
